A study of Rattus norvegicus with 8 samples.

How the data were processed

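RNA from the skin of Long-Evans rat pups was hybridised to 8 arrays in one colour. The pups of the wounded group had received a 3-mm cut in the skin of the back 3 days after birth, and skin was taken at the cut 36 h later. Skin of the control group came from the matching place on pups without a cut. Age and time were recorded here only for the wounded group, so a match in age between the groups was not checked. There were 4 samples per group, and the groups and sample numbers were taken from the labels. The labels do not say that each sample came from a separate animal, so the p-values measure the spread between these samples, which may in part be technical.

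Per the labels, total RNA was amplified into biotin-labelled cRNA and hybridised to Rat MI-Ready arrays, which carry printed oligonucleotides. Per the file headers, the arrays were scanned at 635 nm on a GenePix 4000B scanner with a photomultiplier gain of 650, and spots were read with GenePix Pro 4.1.1.4 without normalization. The deposited scanner files give the intensity of each spot and of its local background on a linear scale. The authors also deposited a table of log2 values for 16198 rows, which name 16079 probes. Set against the scanner files, its values equalled log2 of the median pixel intensity minus the median background plus 1 constant per array, within 0.011 for 99.9% to 100% of the probes compared. Its column medians lay between 6.98 and 7.06. That comparison settles its scale and direction and shows no centring of genes. The rule by which the authors chose its probes is not given in the sources used here.

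The main values were computed from the scanner files with limma 3.58.1 in R 4.3.3. Each array holds 40320 spots, and 1240 of them were left out as blanks, markers, control sequences or spots without a name, after the background correction. The median pixel of each spot was corrected with normexp and an offset of 50, and 65 spots marked bad were left out. The log2 values were quantile normalized, and spots of one probe were averaged. A probe was kept if the software had found its spot on at least 4 of the 8 arrays, which left 19444 of 38948 probes. Probes with the same Ensembl gene ID were represented by the probe with the highest mean signal, and a probe without such an ID stood for itself. This gave 12769 features, 11358 of them with an Ensembl ID. The offset pulls changes of dim probes toward 0, so their fold changes are understated. The number of arrays limits the precision.

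Wounded and control samples were compared with a 2-sided limma test (lmFit, then eBayes with a trend of variance on signal). P-values were adjusted by Benjamini and Hochberg over all features, with a threshold of 0.05. A feature not found on any array of one group has only a bound there, computed from means of normalized log2 values. For the dim group, the higher of the probe's own signal and the lowest signal among found probes was taken on each array.

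The array names its probes by Ensembl or manufacturer IDs. The reference gene table used here, built on the GRCr8 assembly, gives an Ensembl ID in 0 of its 47357 rows, so no Ensembl ID could be matched through it. Of 49127 IDs and name forms of the array, 0 occurred in any of its columns, and the files do not pair them with gene symbols. The 31 gene lists fixed before the data were examined, on interleukin-1 signalling, inflammation, repair, hair follicle and cell types, could therefore not be matched, and their test was not run. The rule for named genes, also fixed then, took the 12 largest rises and the 12 largest falls among named genes past the threshold whose groups did not overlap, members of the gene lists and 2 reference genes. Without gene symbols it was applied to Ensembl IDs by log2 fold change, and only the first 2 of each direction are printed.

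The method was tested on simulated arrays for wounded versus control, with 200 of the 12769 features changed. It recovered 0 of 60 features changed by 0.5 on the log2 scale, 18 of 70 changed by 1 and 59 of 70 changed by 2. Median estimates were 0.29, 0.56 and 1.34. Of 79 calls, 2 were false. The real arrays gave 2255 calls, so the adjustment demanded a smaller unadjusted p in the simulation than there. The shares recovered thus do not carry over to the real arrays. The median residual SD was 0.205 in the simulation and 0.226 in the real arrays, so the simulated noise was slightly smaller than the real noise.

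Alternatives covered the background correction, the normalization, the filter on dim probes, the rule for several probes of an ID, the authors' values, the variance model, array weights, blocks and leaving out each sample. A mean-pixel foreground and a block of 2 arrays outside the common run of array numbers were added after the data had been seen. All 8 arrays were scanned on 1 day, the controls at positions 1 to 4 and the wounded samples at positions 5 to 8. Scan position thus followed the groups and could not be fitted as a separate term. Figures were drawn with matplotlib 3.10.9.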

Results

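In rat pups, 4 skin samples from wounds and 4 from unwounded skin were profiled, the former 36 h after wounding. The study's title links wound healing to protection from hair loss under chemotherapy through interleukin-1β signalling. These arrays address which transcripts differ between wounded and unwounded skin, and no sample received chemotherapy. Between 16930 and 20030 probes per array were found by the scanner software, which is 43.5% to 51.4% of the probes printed. The mean number found was 18734 ± 1373 (SD, n = 4) in controls and 18750 ± 993 (SD, n = 4) in wounded samples (2-sided exact permutation p = 1). Median background intensity was 41 to 44 and the brightest spot of an array reached 27951 to 49584.

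Wounding went with a broad change in the skin transcriptome. Of 12769 features tested, 1023 were higher and 1232 lower in wounded skin. With an offset of 50, 408 features rose and 266 fell at least 2-fold, and 137 rose and 15 fell at least 4-fold. Other settings moved these counts and their ratio. With local background subtracted, 793 rose and 781 fell at least 2-fold, and 365 and 105 at least 4-fold. With the authors' values, which also differ in scaling and in the probes included, 802 rose and 667 fell at least 2-fold, and 339 and 99 at least 4-fold. Thus more features rose than fell at least 4-fold under each of these settings, while the excess at 2-fold nearly vanished with local background subtracted. With the offset of 50, 21 features rose at least 16-fold and the deepest fall was 6.66-fold, a log2 fold change of -2.74 that was -3.58 with local background subtracted. The median change was 1.84-fold among rises and 1.63-fold among falls. The calls rest on limma with Benjamini-Hochberg adjustment. The 4 wounded values lay wholly above or below the 4 control values for 2685 features, or 21.0%, where chance gives 2.86%. With median scaling in place of quantile normalization, 960 features were higher and 761 lower, so the share of higher features among the calls went from 45.4% to 55.8%. That share was 53.6% with cyclic loess and 50.9% with the authors' values.

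**Figure D1:**
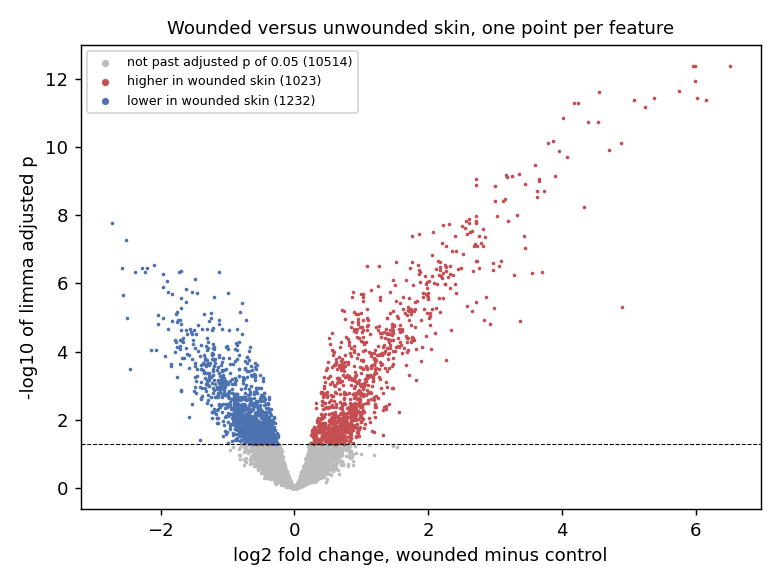
Each point is 1 of 12769 features, placed by its log2 fold change (wounded minus control) and the −log10 of its limma adjusted p. Red points are the 1023 higher and blue points the 1232 lower features, and, with the offset of 50 used here, rises extend further from 0 than falls.

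Large rises were measured for ENSRNOG00000011483 and ENSRNOG00000002792. ENSRNOG00000011483 had the higher fitted value with the offset of 50. Its log2 signal was 6.94 ± 0.21 (SD, n = 4) in control skin and 13.45 ± 0.31 (SD, n = 4) in wounded skin. This is a log2 fold change of 6.51 ± 0.21 (SE), or 91.0-fold, with a limma adjusted p of 4.17e-13, and it was higher in 4 of 4 wounded samples. Its 2 probes gave log2 fold changes of 6.37 and 6.51. ENSRNOG00000002792 was found on 0 of 4 control arrays and 4 of 4 wounded arrays, so its fold change is only a bound. By its brightest probe the fitted rise was 71.3-fold, a log2 fold change of 6.16 (limma adjusted p = 4.13e-12). That bound does not allow for the spread between samples: leaving out wounded 1 gave 5.93. With the mean of its probes the fitted log2 fold change was 5.13. The bound from the brightest probe gives no rank against the first ID. Its wounded log2 signal was 11.998 ± 0.60 (SD, n = 4), and its other probe gave a log2 fold change of 4.11, so its fitted size differs between probes. Whether the change itself differs between them was not tested.

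With the offset of 50, the deepest fall was that of ENSRNOG00000029792, from a log2 signal of 9.66 ± 0.12 (SD, n = 4) to 6.93 ± 0.34 (SD, n = 4). Its log2 fold change was -2.74 ± 0.20 (SE), 6.66-fold lower, with a limma adjusted p of 1.73e-08, and 1 of its 2 probes was tested. ENSRNOG00000006930 went from 10.29 ± 0.36 (SD, n = 4) to 7.70 ± 0.42 (SD, n = 4). Its log2 fold change was -2.58 ± 0.24 (SE), 5.99-fold lower, with a limma adjusted p of 3.62e-07, and its 2 probes gave -2.58 and -1.97. The files do not pair these IDs with gene symbols.

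**Figure D2:**
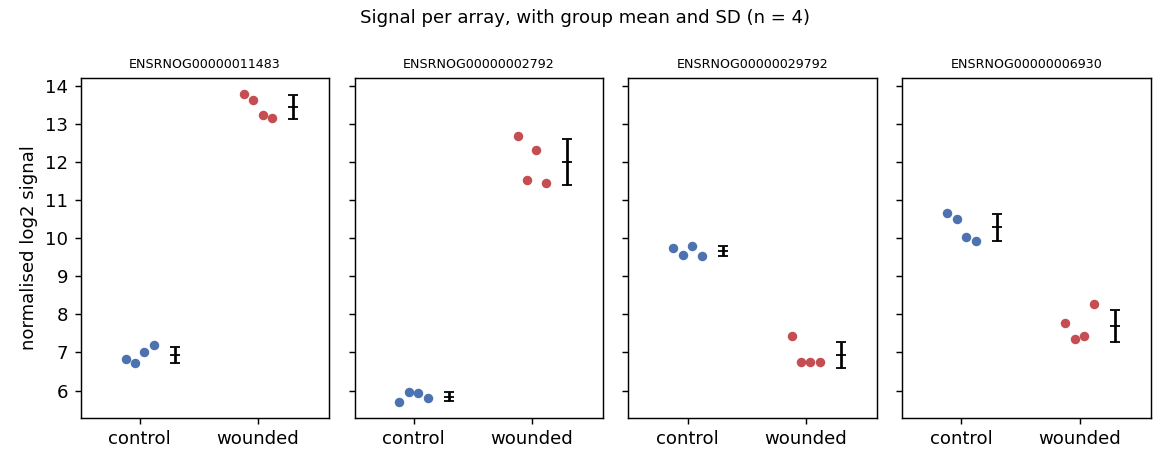
Normalised log2 signal of 4 Ensembl IDs on each array (points), with the group mean and SD (bars, n = 4). The groups do not overlap for any of the 4 IDs, and the first ID spans a mean of 6.94 in control to 13.45 in wounded skin.

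Some transcripts passed between not found and found. Among tested features, 162 were found on all 4 wounded arrays and on 0 control arrays, and 158 of them passed the limma test. The reverse held for 46 features, of which 34 passed. In the other ways of parting the 8 arrays into 4 and 4, the highest such count was 30. Being found and passing both rest on the same spots, so passing is no separate support for these features. Of all tested features, 17.7% passed.

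Different probes of one Ensembl ID mostly moved together. For 5595 IDs with at least 2 tested probes, the log2 fold changes of the 2 brightest probes had a Pearson r of 0.790 and a Spearman rho of 0.598 across IDs, which are not independent replicates. Where the brightest probe passed the limma test, the next one had the same sign in 1012 of 1059 IDs, or 95.6%. The probes were read on the same arrays, and where the brightest probe had an adjusted p above 0.5 in limma, the signs agreed in 56.3% of IDs. Both passed in 610 IDs, with the same direction in 608 and opposite directions in 2. With only probes found on all 8 arrays, the same direction held in 303 IDs and opposite directions in 1. Leaving out 1 sample in turn gave 0 to 4 IDs with opposite directions, the 4 without control 1 and the 0 without wounded 1 or wounded 4.

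**Figure D3:**
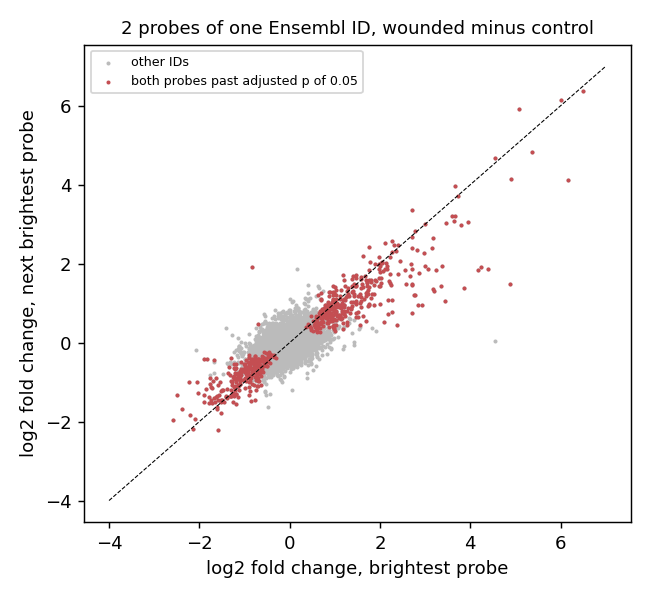
Log2 fold change (wounded minus control) of the brightest probe of an Ensembl ID on the horizontal axis and of its next brightest probe on the vertical axis. In the 610 IDs where both passed (red), 608 lie in a shared direction. The dashed line marks equal change.

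Samples of one group resembled each other more than samples of different groups. Pearson r across features was 0.961 to 0.981 between controls, 0.955 to 0.978 between wounded samples and 0.883 to 0.936 between groups, and features are not independent replicates. The first principal component held 57.7% of the variance and parted the groups. The second held 13.5% and set control 1 and wounded 4 apart from the other 6 arrays. By the numbers in the labels, these are also the 2 arrays outside a common run that holds 3 controls and 3 wounded samples. Control 1 is numbered below that run and wounded 4 above it, so they share no number range. Within that run of 6, 958 features were higher and 1156 lower. With these 2 arrays as 1 block, 1188 were higher and 1561 lower.

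**Figure D4:**
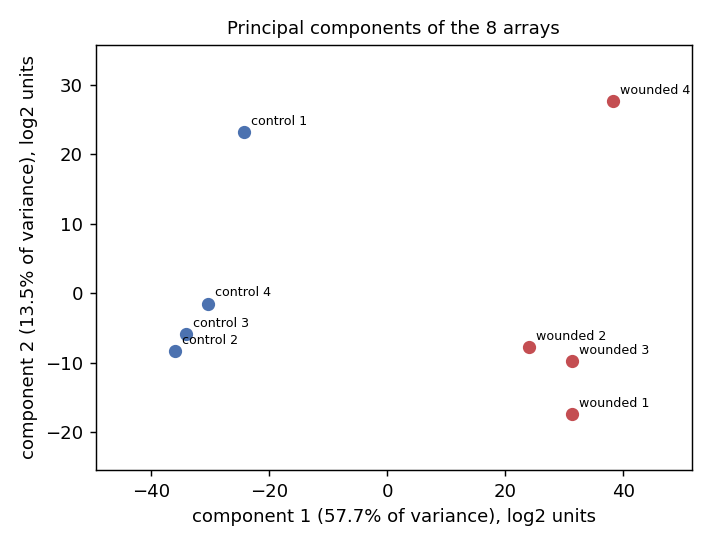
Arrays placed by the first and second principal components of their normalised log2 values, blue for control and red for wounded. The first component (57.7%) parts the groups and the second (13.5%) sets control 1 and wounded 4 apart.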

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

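In 28 sets of 4 samples, 3 values stood far from the other 3 of their group. Chance sets apart about 1 in 20 such sets. Wounded 1 had 55 spots marked bad, against 2 to 3 on the other wounded arrays. The median background of control 3 was 44, against 43 on the other controls, a difference of 1 intensity unit. The log2 signal of ENSRNOG00000029792 was 7.44 in wounded 1, against 6.75 to 6.76 in the other wounded samples.

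Control 1 and wounded 4 deviated from their group means together. The test on array numbers was chosen only after the result was seen. The correlation of their deviations across features was 0.403, and the next highest of the 16 control-wounded pairs had 0.148. After a smooth trend with signal was removed from each array, the correlation was 0.404 (95% bootstrap interval 0.385 to 0.424). A signal-dependent scaling error left by the quantile normalization is thus argued against. That normalization had already matched the signal distributions of the arrays, so the test had little such error to detect. A change in the transcripts themselves would be expected in other probes of the same ID. The deviations of 2 probes of one ID correlated only 0.041 more than those of brightness-matched probes of other IDs (95% bootstrap interval 0.00073 to 0.082). This goes with a probe-specific effect, but its source, printing or other, was not tested. The excess that a transcript change of this size would give was not measured, so such a change is not excluded. Both intervals in this paragraph resample features or IDs, not samples. That these 2 arrays lie outside the common run of numbers may be related. They lie on opposite sides of that run, though, and share no number range. The rank of 1 pair in 16 cannot settle the question, and no biological explanation beyond a change in the transcripts was tested.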

How the results depend on the processing

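The mean-pixel foreground and the block of 2 outlying arrays were chosen after the data had been seen. Of 273 values over 23 alternatives, 243 stayed within 1.5 times the main count or kept their direction and side of the threshold, 30 counts moved further and 0 reversed. Of the main calls that an alternative tested, 73.9% still passed with the same sign without control 2, 75.5% with median scaling, 76.5% without control 3 and at least 78.7% under each other alternative. With probes found on all 8 arrays (fewer features), 625 were higher, 269 at least 2-fold and 85 at least 4-fold. Median scaling gave 761 lower. Other settings moved the counts of large changes. With an offset of 10, 649 were higher and 485 lower at least 2-fold, and 227 and 41 at least 4-fold. Plain background subtraction gave 793, 781, 365 and 105, and the authors' values 802, 667, 339 and 99. Without background correction, which adds no offset either but keeps the background in the signal, the counts were 473, 302, 153 and 19. The mean of an ID's probes gave 9 at least 4-fold lower. The cause of these moves was not tested.

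Leaving out 1 sample in turn gave 842 to 1056 higher and 880 to 1325 lower, 405 to 461 and 244 to 298 at least 2-fold, and 125 to 152 and 12 to 22 at least 4-fold. The 4 named IDs kept their direction and call in every alternative that tested them. Log2 fold changes ranged from 6.39 to 7.50 for ENSRNOG00000011483, -3.58 to -2.64 for ENSRNOG00000029792 and -3.0 to -2.27 for ENSRNOG00000006930. For ENSRNOG00000002792, which has only a bound, the lowest fitted value was 5.13. The largest adjusted p among these alternatives was 3.89e-05. With the sample number as a replicate block, 987 were higher and 1079 lower. Same-numbered samples had deviations correlated at -0.28 to -0.01, and 0 of 8 samples correlated best with their own number. No pairing by number was thus seen. These values cannot exclude one, since deviations sum to 0 within each group and control 1 and wounded 4 deviated together. The gene list test and its 8 alternatives were not run, since no list could be matched. Between 43.5% and 51.4% of the probes were found per array, so dimmer transcripts are poorly measured.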

Other observations

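The tests comparing shares of 2-fold and 4-fold changes between rises and falls were chosen only after the result was seen. The real split of the samples into 4 and 4 gave 2255 features, and 1 of the 35 splits, the real one, gave as many. The highest count in any other split was 0. For changes of at least 2-fold the real split gave 674, again 1 of 35, with 0 as the highest other. The share of 1 in 35 is the smallest these splits can give, and any clear difference between the groups would reach it. It argues against chance only if the 8 samples are independent, which the labels do not state. Nor does it part wounding from scan position, which followed the groups. The counts of 0 are no measure of size, since a split that mixes the groups adds their difference to the spread.

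With an offset of 50, rises were larger than falls. With local background subtracted, 793 rose and 781 fell at least 2-fold, and 365 and 105 at least 4-fold, so the ratio of rises to falls was lower at each size. A signal floor that shortens falls is a candidate explanation. Among features whose brighter group had a mean log2 signal of at least 10, the median rise exceeded the median fall by 0.286 (95% bootstrap interval 0.040 to 0.559), which reaches below the bound of 0.1 set beforehand and leaves the floor open. In the same features 107 of 164 rises and 119 of 198 falls were at least 2-fold (2-sided Fisher's exact p = 0.328), and 57 and 7 were at least 4-fold (p = 1.45e-15). In these bright features a floor is thus not the whole cause of the 4-fold excess. Dimmer features, where a floor would act most, were left out of this test, so its part in the excess over all features stays open. Transcripts not found in unwounded skin might also give large rises: of the 137 features that rose at least 4-fold, 27, or 19.7%, were found on 0 control arrays (95% exact interval 13.4% to 27.4%, which crosses the bound of 25% set beforehand). Among features found on all 8 arrays, 83 of 617 rises and 13 of 895 falls were at least 4-fold. The 2-sided Fisher's exact p was 2.61e-21, with features again taken as independent. Transcripts not found in unwounded skin are thus not the whole cause of the 4-fold excess.

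Fold sizes differed between probes of one ID. In 1189 IDs called on the mean of their probes, the dimmer of the 2 brightest probes had the smaller change in 71.99%. The 95% exact interval, with IDs taken as independent, was 69.3% to 74.5%. This share goes with compression of dim signals. The median ratio of the dimmer to the brighter probe's change was 0.775 with an offset of 50 and 0.885 with an offset of 10. The share was still 66.5% in 546 IDs whose probes differed by under 0.5 on the log2 scale, so brightness may not be the only reason. In 90 IDs whose probes differed by 2 or more it was 70%, and the median ratio with an offset of 50 was 0.719, against 0.847 in the 546 IDs. With an offset of 10 the order was the opposite, 0.945 against 0.905.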
